A study of Homo sapiens with 14 samples.

How the data were processed

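Guide abundance was measured by sequencing amplified guide cassettes from genomic DNA of H9 cells, an established human pluripotent stem cell line. Per the labels, the cells carried a doxycycline-inducible Cas9 and a pooled library of guides against transcription factors. They were differentiated to cardiomyocytes in 2D or in 3D, and the day 25 cells were sorted on cardiac troponin T (TNNT2). The 14 libraries fall into 5 groups: undifferentiated cells at day 0 (2 replicates), and TNNT2- and TNNT2+ cells of each system at day 25 (3 replicates each). The labels' protocols call the 3 differentiations biological replicates and say that these were sorted into both fractions, so a shared replicate number was taken to mark 1 differentiation. Residual correlations of same-numbered fractions were 0.0767, 0.108 and 0.126 in 2D and 0.109, 0.0560 and 0.0736 in 3D. Each library correlated best with its own number, but not every pair exceeded 0.1, so the pairing rests on the protocols, and this reading was settled after the fits with a replicate block had been seen. The main sort fits have no block. For the day 0 libraries nothing says whether they came from separate cultures, so their spread may be technical.

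The authors deposited 2 tables, for 2D and for 3D, each with its own scaling of the same day 0 libraries. Their values are a normalized signal per guide and, as the deposited values show, each is a read count divided by 1 size factor per library. Guide analysis used MAGeCK, per the submitters' processing notes, which also name the build hg38. Its version and normalization setting are not given in the sources used here. Dividing each column by its smallest value above 0 gave whole numbers within 0.001 for 100% of values, with a largest deviation of 1.38e-10. In 8 of the 16 columns there were at least 100 low values to test this on, and reads recovered from all columns were used for totals and count tests. Each library held between 22355936 and 31671019 reads. PCR reads carry no molecular identifiers here, so read depth does not give the number of DNA molecules sampled.

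The tables held 11364 guides, of which 100 were controls, and 1633 target names, 1574 of them with 7 guides. As symbols, 1612 names matched the GRCh38.p14 gene table, and the others were kept as deposited. TBXT is listed under its older symbol T. The design fixed before the data were examined named edgeR's quasi-likelihood test on raw counts. Because the deposited values are normalized, the main guide test was instead limma (version 3.58.1) with a mean-variance trend on log2(value + 10), and edgeR (version 4.0.16) on recovered reads became an alternative. Log2 fold changes are on this pseudocount scale, which understates changes of low guides. Guides needed a mean value of at least 10, and genes at least 3 such guides, which left 1621 genes. Guide p-values were combined per gene and direction by a rebuilt version of MAGeCK's robust rank aggregation, since MAGeCK itself was not run. Guides with a 1-sided p under 0.25 entered, and p came from 100000 random guide sets, so that 1e-05 is the smallest it can give. For a gene called alone among 1621, the smallest adjusted p is then 0.0162. Each further random set that ranks as high raises it by as much, so calls gained or lost near 0.05 rest on few sets. Benjamini-Hochberg adjustment ran over genes within each direction, with calls at 0.05.

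Sort ratios are TNNT2- over TNNT2+. For day 25 against day 0, the deposited values of both fractions with the same replicate number were averaged, in place of the sum of counts that the design named, which would not match the day 0 scale. The test of 3D against 2D used recovered reads scaled together by median ratios, as the tables were normalized separately. Gene lists were tested over guides with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry beside it, on the log2 values rather than the voom values the design named. Adjustment ran over the 28 tests of 14 lists in both sorts. Of 163 genes in the fixed lists, 7 had no guides: CTNNB1, LMO2, MYOCD, SMAD2, SMAD6, SMAD7 and TFAM. TNNT2 itself was not targeted. Guide inequality was summarised by the Gini index and compared by exact permutation tests.

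Named genes followed a rule fixed before the data were examined: the 10 leading genes per direction in each sort, 8 lower and 4 higher genes per system at day 25, 5 per side for the difference between systems, 2 leading members of each list in each sort, and a set of cardiac and control genes. The text gives a selection of these, and some named genes are not reported here. A gene's value is the median log2 fold change of its guides with the SD over guides, and its CPM summed over guides. The scripts were tested on simulated negative binomial reads with 200 changed genes. Alternatives covered scaling, filters, thresholds, DESeq2 (version 1.42.0), summed guides, fry, a rebuilt MAGeCK guide test, a replicate block and each library left out. Pseudocounts of 1 and 100, TMM factors, edgeR on recovered reads, array weights, list tests at day 25 against day 0, the split of the day 0 libraries and fits without 3 thinly represented 3D libraries were chosen after seeing the data. R was version 4.3.3.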

Results

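Guide cassettes of a pooled transcription factor knockout library were counted in 14 libraries from H9 pluripotent stem cells and their cardiomyocyte cultures. The design asks which knockouts shift cells between the TNNT2+ fraction, which expresses cardiac troponin T, and the TNNT2- fraction. Library totals lay between 22355936 and 31671019 reads for 11364 guides, so depth per guide was high throughout. Guide representation differed much more. In 2D, between 0.502% and 3.19% of guides had fewer than 10 reads, and the mean Gini index was 0.356 ± 0.0127 (SD, n = 3) in TNNT2- and 0.374 ± 0.0311 (SD, n = 3) in TNNT2+ libraries. In 3D it was 0.504 ± 0.127 (SD, n = 3) and 0.501 ± 0.164 (SD, n = 3). The share of guides under 10 reads reached 32.5% in day 0 replicate 2, 27.6% in 3D TNNT2- replicate 3 and 43.6% in 3D TNNT2+ replicate 3, and was 11.1% in 3D TNNT2- replicate 2. Between the sorted fractions, exact permutation tests (2-sided) of the Gini index gave p = 0.6 in 2D and p = 1 in 3D, and could not have gone below 0.1 with 3 libraries against 3. Between systems it was higher in 3D over 6 libraries each (exact permutation test, 2-sided, p = 0.0108). Averaged per replicate number, the exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. The higher 3D mean came from the 3D libraries just named. The index was 0.367 in 3D TNNT2- replicate 1, and 0.410 and 0.403 in 3D TNNT2+ replicates 1 and 2. In 2D it reached 0.410, in TNNT2+ replicate 1.

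**Figure D1:**
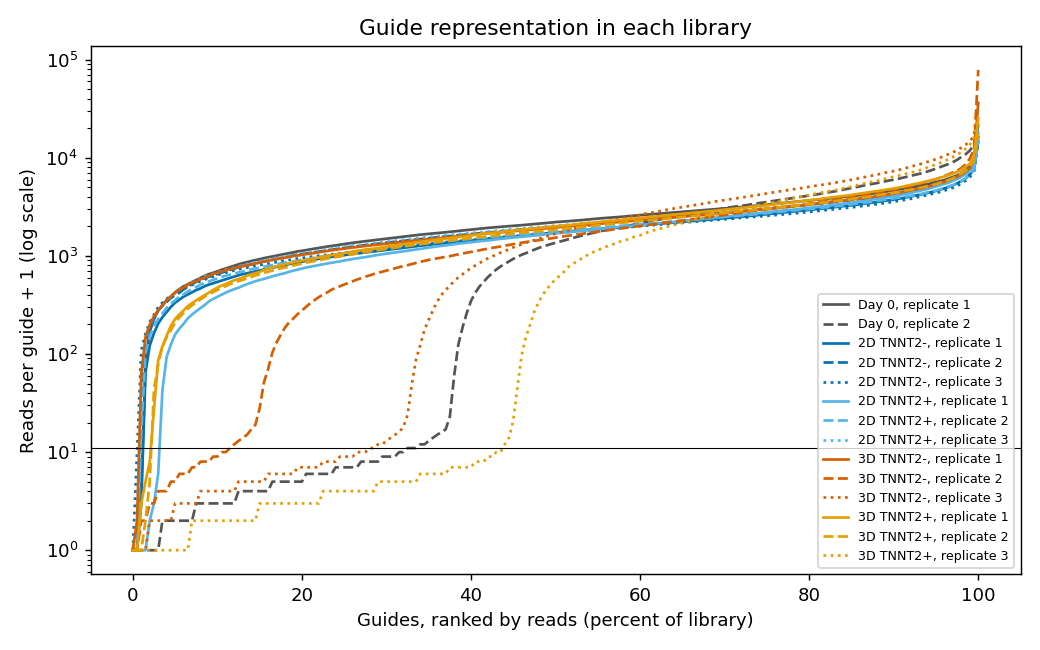
Reads per guide plus 1 (log scale) against the guide's rank as a percent of the library, 1 line per library, with colours for groups and line styles for replicates. The horizontal line marks 10 reads, and the day 0 replicate 2, 3D TNNT2- replicate 3 and 3D TNNT2+ replicate 3 lines cross it at 32.5%, 27.6% and 43.6% of guides.

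Replicates resembled each other more in 2D than in 3D. Across guides, Pearson correlations of log2 CPM (reads scaled to the library total) were 0.561 to 0.636 among 2D TNNT2- and 0.488 to 0.579 among 2D TNNT2+ replicates. They were 0.239 to 0.415 among 3D TNNT2- and 0.241 to 0.456 among 3D TNNT2+ replicates, and 0.291 between the day 0 libraries. The 3D value of 0.456, between TNNT2+ replicates 1 and 2, is the only one without a thin library (TNNT2- replicates 2 and 3, TNNT2+ replicate 3). Replicate 1 of 3D TNNT2- and of 3D TNNT2+, read as fractions of 1 differentiation, correlated at 0.587. In 2D the same-numbered fractions correlated at 0.499, 0.626 and 0.701. All other 3D replicate values involve a thin library, but 0.456 still lay below the range of either 2D fraction. It is 1 pair, so whether the systems themselves differ was not settled. Guides are not independent replicates. In simulated reads with the dispersion of each comparison, 68.7% of genes changed 2-fold and 98.5% of genes changed 4-fold were called in the 2D sort. In the 3D sort these shares were 0% and 8.96%. At day 25 against day 0 they were 5.97% and 43.3% in 2D, and 0% and 20.9% in 3D, so that most changes of these sizes would be missed there. Benjamini-Hochberg adjustment is more lenient where many genes change. These shares may therefore overstate what would be called where few genes change, in the 2D sort too. The draws were negative binomial and lack the separate low mode of single libraries such as day 0 replicate 2 and 3D TNNT2+ replicate 3. How this bears on the 3D and day 25 shares was not tested.

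In the 2D sort no targeted gene passed the threshold in either direction. The leading gene toward TNNT2+ was MSANTD4, with a median log2 fold change of -0.71 ± 0.56 (SD over 7 guides), all 7 guides lower in TNNT2- cells, and an adjusted p of 0.162 by limma and rank aggregation. Its guides summed to 499.7 ± 32.7 CPM (SD, n = 3) in TNNT2- and 818.8 ± 243 CPM (SD, n = 3) in TNNT2+ cells. OSR1, a regulator of intermediate and lateral mesoderm, had a value of -0.66 ± 0.53 with 7 of 7 guides lower, and ZNF107 had -1.03 ± 1.17. Toward TNNT2-, ZBTB42 had 0.88 ± 0.86, the sinoatrial regulator SHOX2 0.84 ± 1.30, the forkhead factor FOXO1 0.50 ± 0.45 and the chromatin remodeller BPTF 1.13 ± 0.73. The smallest adjusted p toward TNNT2- was 0.596, but without 2D TNNT2- replicate 3 FOXO1 passed at 0.88 (adjusted p = 0.0162, limma). At an unadjusted p under 0.05 there were 86 genes toward TNNT2- and 84 toward TNNT2+, against 81.05 per direction by chance. With DESeq2 at the guide level 0 genes were called toward TNNT2- and 1 (MSANTD4) toward TNNT2+, and edgeR on recovered reads called 0 in both. No single guide passed with limma, and 3.34% of 11346 guides had an unadjusted p under 0.05.

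Core cardiac regulators did not pass in 2D. NKX2-5, a homeobox factor of early heart development, had a median log2 fold change of -0.43 ± 0.58, with 661.8 ± 51.3 CPM (SD, n = 3) in TNNT2- and 808.1 ± 61.6 CPM (SD, n = 3) in TNNT2+ cells and an adjusted p of 0.859 by limma and rank aggregation. GATA4 had -0.36 ± 0.80, TBX5 0.01 ± 0.45, HAND1 0.32 ± 0.55, HAND2 0.34 ± 0.75, MEF2C 0.30 ± 0.42 and ISL1 0.21 ± 0.67. The mesoderm regulators MESP1, EOMES and T had 0.37 ± 0.51, 0.36 ± 1.15 and 0.13 ± 0.70. The pluripotency factor POU5F1 had -0.17 ± 0.50 and ZNF711 0.06 ± 0.64. With each library left out in turn none of these 12 genes passed, and 6 kept their sign in every fit. MEF2C then ranged from 0.03 to 0.37, EOMES from -0.12 to 0.51 and TBX5 from -0.39 to 0.43. MESP1 ranged from 0.04 to 0.38, T from -0.07 to 0.30 and HAND2 from -0.003 to 0.86.

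In the 3D sort 1 gene, FOXO1, passed toward TNNT2- and none toward TNNT2+. FOXO1, a transcription factor restrained by insulin and AKT signalling, lies on chromosome 13 from 40555667 to 40666641 (GRCh38). Its median log2 fold change was 0.86 ± 2.09 (SD over 7 guides), with 5 of 7 guides higher in TNNT2- cells and an adjusted p of 0.0162 by limma and rank aggregation. Its guides summed to 2485 ± 1085 CPM (SD, n = 3) in TNNT2- and 1113 ± 265 CPM (SD, n = 3) in TNNT2+ cells. Leaving out any 1 of the 6 libraries ended this call, with adjusted p from 0.0648 to 0.778 and medians from 0.32 without 3D TNNT2- replicate 2 to 2.41 without 3D TNNT2- replicate 3. With a replicate block, which pairs the fractions of a differentiation, FOXO1 did not pass (adjusted p = 0.616, limma) and KDM5B passed toward TNNT2+. edgeR on recovered reads put FOXO1 at 1.67 and did not call it (adjusted p = 0.605), and called JUNB instead. DESeq2 put it at 1.85 (adjusted p = 0.926) and called no gene. At an unadjusted p under 0.05 there were 74 genes toward TNNT2- and 93 toward TNNT2+, and no single guide passed with limma.

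**Figure D2:**
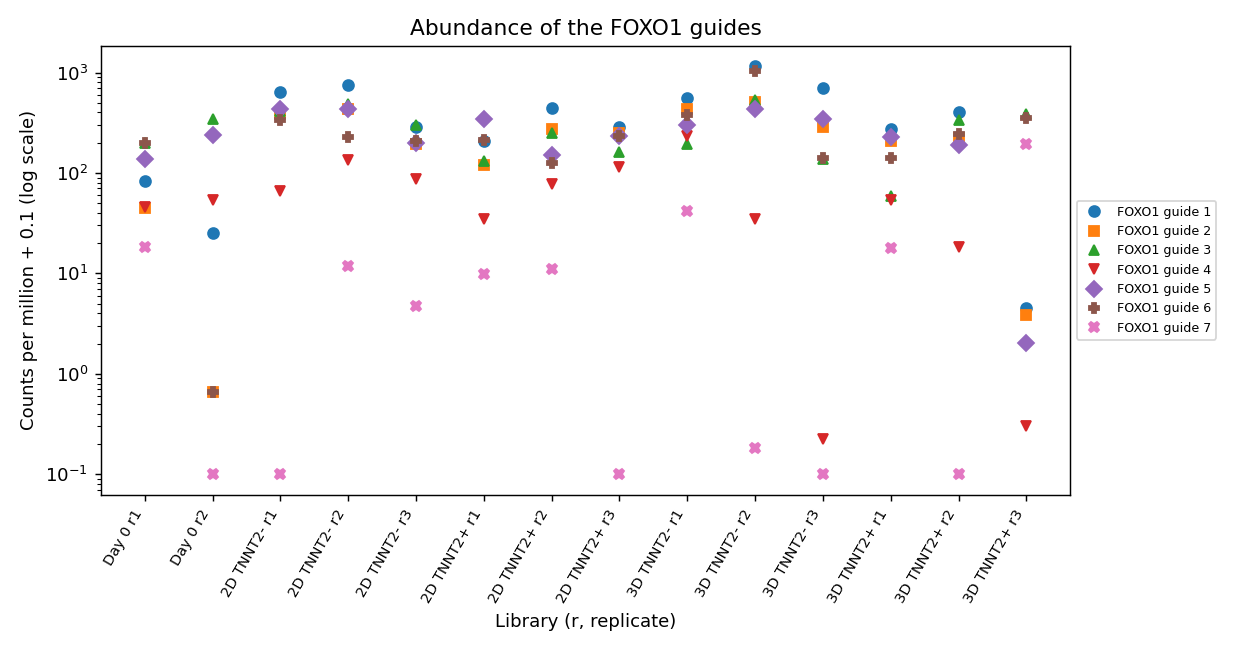
CPM plus 0.1 (log scale) of each of the 7 FOXO1 guides in each library, 1 marker shape per guide. In 3D TNNT2+ replicate 3, guides 1, 2 and 5 lie at 4.45, 3.76 and 1.92 CPM, while guide 7 lies at 193.8 CPM there.

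Other leading genes of the 3D sort did not pass. ARHGAP35 had a median log2 fold change of 1.37 ± 1.95 and an adjusted p of 0.259 by limma and rank aggregation. It passed with control guide scaling and with TMM factors (adjusted p = 0.0486 each, limma) and with array weights (0.0162). It also passed at 1.29 without the 3 thin libraries (0.0162), a fit with 1 TNNT2- library. Without any 1 of the 6 libraries its value lay between 0.21 and 1.25, with no call. MEF2C, a MADS-box factor of muscle development, had 2.51 ± 0.76 with 7 of 7 guides higher in TNNT2- cells and an adjusted p of 0.619 by limma and rank aggregation. In 3D TNNT2+ replicate 3, 6 of the 7 MEF2C guides had fewer than 10 reads, and without that library the MEF2C value was 1.07. Without the 3 thin libraries it was 0.34, with 4 of 7 guides higher. Toward TNNT2+, the histone demethylase KDM5B had -2.97 ± 1.53 and an adjusted p of 0.313, and without 3D TNNT2- replicate 3 it passed, at -3.37 with an adjusted p of 0.0162 by limma. It also passed with a replicate block, and with array weights at -1.97, each with the same adjusted p. Without 3D TNNT2- replicate 2 it was -1.28 (adjusted p = 0.886), and without the 3 thin libraries -0.47 (0.913). ZZZ3, BATF and NFYA had -2.91 ± 2.63, -2.87 ± 1.43 and -2.71 ± 1.5, and without the 3 thin libraries -0.44, -0.20 and 0.45. Among the core regulators, GATA4 had 1.93 ± 2.21, NKX2-5 0.44 ± 1.71, TBX5 -0.15 ± 1.91, HAND1 -0.64 ± 1.38, HAND2 -0.23 ± 1.93 and ISL1 -1.22 ± 1.14. With each library left out in turn, 3 of the 12 cardiac and control genes named in 2D (GATA4, HAND2 and MEF2C) kept their sign in every fit. GATA4 then ranged from 0.58 to 3.26, HAND2 from -1.03 to -0.14 and NKX2-5 from -0.005 to 1.24. TBX5 ranged from -1.76 to 0.69, HAND1 from -0.98 to 0.09 and ISL1 from -1.88 to 0.11. NANOG had -2.56 ± 1.16 with all 7 guides lower in TNNT2- cells, and an adjusted p of 0.717, and lay at -0.45 without the 3 thin libraries.

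None of the 14 gene lists passed the test of a shift against the other guides in either sort, with a smallest adjusted p of 0.910 by camera and 0.838 with an estimated correlation. The smallest adjusted p by fry, which tests a list against no change and not against other guides, was 0.577. In 2D, 11 of 18 cardiac factors lay toward TNNT2-, with a median guide log2 fold change of 0.06. Mesendoderm and cardiac mesoderm factors lay toward TNNT2- in 10 of 15 cases (median 0.15), and WNT, NODAL and BMP effectors in 6 of 10 (0.08). Endoderm factors did so in 10 of 12 (0.08), led by FOXA2 at 0.57 ± 0.76. Endothelial and blood factors lay the other way, toward TNNT2+, in 9 of 13 cases. Medians were -0.03 for endothelial and blood, -0.10 for epicardial and stromal, 0.01 for neural and skeletal muscle, -0.02 for pluripotency, -0.05 for retinoic acid and second heart field, 0.01 for metabolic and hypoxia and 0.02 for commonly essential factors. They were -0.05 for HOX genes, -0.02 for ZNF genes and -0.04 for control guides. The pluripotency, retinoic acid, HOX and ZNF lists had negative medians and positive means, and the metabolic list had a positive median although camera placed it lower than the other guides. In 3D the medians, in the same order, were -0.10 for cardiac, -0.22 for mesendoderm, -0.33 for WNT, NODAL and BMP, -0.22 for endoderm, 0.02 for endothelial, 0.21 for epicardial and 0.24 for neural factors. They were -0.29 for pluripotency, -0.12 for retinoic acid, -0.48 for metabolic, -0.24 for commonly essential factors, -0.33 for HOX genes, -0.11 for ZNF genes and 0.09 for control guides, against -0.13 over all guides. There the cardiac list had a negative median and a positive mean, and the WNT and endoderm lists had negative medians although camera placed them higher than the other guides. Cardiac, mesendoderm, WNT and endoderm members lay toward TNNT2- in 8 of 18, 6 of 15, 2 of 10 and 6 of 12 cases in 3D. Adjusted over the list alone, OSR1 passed in the epicardial list in 2D, and MEF2C in the cardiac and NFYA in the commonly essential list in 3D. Over all genes tested none of these 3 passed.

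The sort ratios of both systems showed no correlation across 1621 genes (Pearson r = 0.007, Spearman rho = 0.004), and 49.0% of genes had the same sign. In the 3D sort the median standard error of a guide was 2.18 log2 units, above the SD of 1.95 over all guides. Noise of this size can hide shared effects, so the lack of correlation does not show that the systems differ. The test of the difference between systems, with all libraries, called no gene with limma and rank aggregation, with 77 and 93 genes at an unadjusted p under 0.05. MEF2C and FOXO1 led toward a higher ratio in 3D, at 2.51 ± 0.86 and 0.40 ± 1.85. MEF2C lay at 0.85 without 3D TNNT2+ replicate 3 and at 0.20 without the 3 thin libraries. FOXO1 ranged from -0.16 without 3D TNNT2- replicate 2 to 1.90 without 3D TNNT2- replicate 3. KDM5B and ZZZ3 led toward a higher ratio in 2D, at -3.32 ± 1.70 and -3.02 ± 2.89. Without 3D TNNT2- replicate 3 KDM5B passed, at -3.41 with an adjusted p of 0.0162 by limma, and without the 3 thin libraries it lay at -0.66 (0.947). FOXO1's call in 3D was therefore not shown to differ from its value in 2D.

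**Figure D3:**
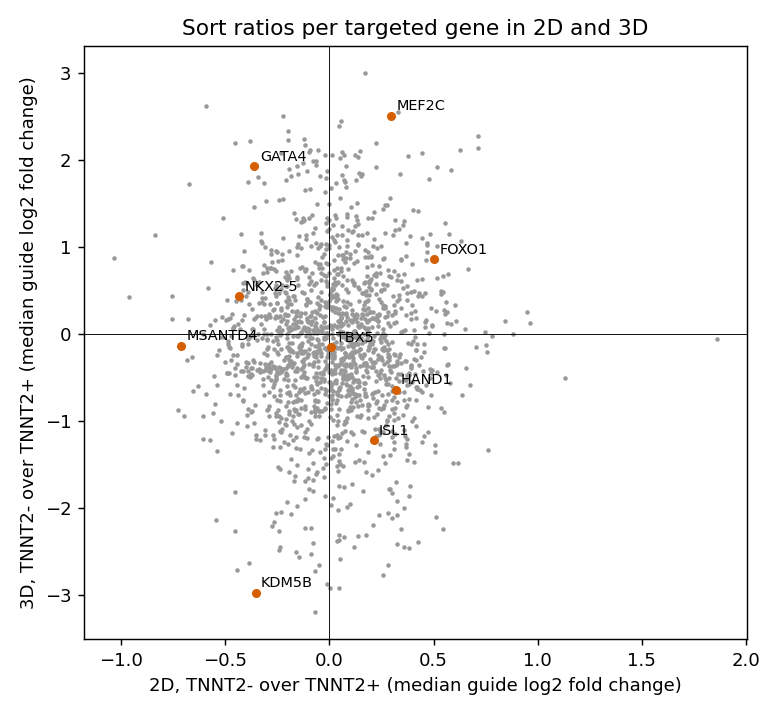
Median guide log2 fold change of TNNT2- over TNNT2+ cells in 3D (vertical) against 2D (horizontal), 1 grey point per targeted gene, with 9 named genes in orange. The points form no diagonal (Pearson r = 0.007), and FOXO1 lies at 0.50 in 2D and 0.86 in 3D.

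Day 25 cells were compared with day 0 to see which knockouts were gained or lost over differentiation. In 2D, FOXO1 guides passed as higher at day 25, with a median log2 fold change of 0.88 ± 2.04, 6 of 7 guides higher and an adjusted p of 0.0162 by limma and rank aggregation. They summed to 697.5 ± 43.7 CPM (SD, n = 2) at day 0, against 2012 ± 643 CPM (SD, n = 3) in 2D TNNT2- and 1223 ± 144 CPM (SD, n = 3) in 2D TNNT2+ cells. The size of this change depended on the pseudocount, as it was 2.41 with 1 and 0.27 with 100 in place of 10, and it passed with both. Its value was 0.35 without 2D TNNT2- replicate 3 and 0.41 without 2D TNNT2+ replicate 1, and it passed in both. Without day 0 replicate 1 no gene passed and FOXO1 lay at 3.17 (adjusted p = 0.820). Without day 0 replicate 2 it passed at 0.84 (adjusted p = 0.0486). edgeR and DESeq2 called ZBTB20 and not FOXO1. No gene passed as lower at day 25 in 2D. ZBTB7A led there at -1.26 ± 2.41 (adjusted p = 0.162), followed among others by YBX1 at -1.19 ± 0.76 with 7 of 7 guides lower. In 3D no gene passed in either direction. FOXO1 had 2.58 ± 2.68, ZNF10 1.61 ± 2.43, the caudal homeobox gene CDX2 3.61 ± 0.88 and FOXI3 3.58 ± 1.43, each with an adjusted p of 0.0932 by limma and rank aggregation. Without day 0 replicate 2 these values were 1.38, 0.88, 1.10 and 0.65, with adjusted p of 0.914 or more. FOXO1 passed without 3D TNNT2+ replicate 3, at 0.66 with an adjusted p of 0.0162, and without 3D TNNT2+ replicate 2, at 2.61 with an adjusted p of 0.0486. FOXK1 led toward loss at -1.94 ± 1.82. At an unadjusted p under 0.05 there were 78 higher and 70 lower genes in 2D, and 73 and 85 in 3D. Single guides were less balanced (limma, unadjusted p under 0.05), with 280 higher and 450 lower in 2D, and 505 and 21 in 3D. The median over all guides was 0.08 in 2D and 0.41 in 3D, where 1 guide passed as higher. No list passed (smallest adjusted p = 0.921 by camera).

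Both day 25 comparisons share the day 0 libraries. Their gene values correlated (Pearson r = 0.764, Spearman rho = 0.752, across genes) with a covariance of 1.02. Simulated unchanged groups gave r = 0.380 and a covariance of 0.148, but these draws lack the separate low mode of day 0 replicate 2. The difference between the day 0 libraries themselves gave a covariance of 1.66, above the observed one. The correlation was therefore no larger than shared controls can give. Set against 1 day 0 library each, with none shared, the systems showed r = 0.015 (2D against replicate 1, 3D against replicate 2) and r = -0.045 the other way round, with covariances of 0.0118 and -0.0663. This split was chosen after seeing the data.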

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

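Counts of calls were 0 or 1 in each comparison, so a change of 1 gene moves them. Pseudocounts of 1 and 100, TMM factors, array weights, edgeR on recovered reads and the fits without 3 thin 3D libraries were chosen after seeing the data. In the 2D sort, 1 gene (MSANTD4) passed toward TNNT2+ with DESeq2 and without each gene's strongest guide, and DESeq2 called 12 and 6 guides toward TNNT2- and TNNT2+. The rebuilt MAGeCK guide test called 84 guides toward TNNT2- in 2D and 1038 in 3D, 0 toward TNNT2+ in either, and 0 genes in both sorts. It takes its variance from the TNNT2+ libraries alone. This bounds the score of a guide that is lower in TNNT2- cells but not of a higher one. In the 3D sort, 0 genes passed toward TNNT2- with DESeq2 size factors, DESeq2, summed guides and fry, and 2 (FOXO1 and ARHGAP35) with control guide scaling, TMM factors and array weights, the last of which also called 1 gene (KDM5B) toward TNNT2+. Guides called in 3D were 10 and 14 with DESeq2, 1 toward TNNT2+ with DESeq2 size factors, 3 toward TNNT2- with control guide scaling and TMM factors, and 2 with array weights. In 2D at day 25, 0 genes passed with summed guides and fry, and 2 with a pseudocount of 100. In 3D at day 25, 1 gene passed with control guide scaling, TMM factors, array weights and either fraction alone. It was ZNF10 with the TNNT2+ libraries alone and FOXO1 in the other 4 settings. With a pseudocount of 100, 2 genes passed, and 4 did at an adjusted p of 0.10. The correlation of sort ratios was 0.0417 with DESeq2 size factors and -0.0197 without 3 thin 3D libraries. The mean Gini index of 2D TNNT2- libraries was 0.333 over guides with 50 reads in both day 0 libraries. The cause of these changes was not tested.

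Leaving out 1 library at a time gave 0 to 1 genes toward TNNT2- in 2D (FOXO1 without 2D TNNT2- replicate 3), 0 toward TNNT2- and 0 to 1 toward TNNT2+ in 3D (KDM5B without 3D TNNT2- replicate 3), 0 to 1 at day 25 in 2D and in 3D, and 0 to 1 for the difference toward 2D (KDM5B without 3D TNNT2- replicate 3). The correlation ranged from -0.0482 to 0.0368. With 1 day 0 library left, it is assumed to vary like the day 25 cultures, and the 1 TNNT2- library left without the 3 thin ones like the TNNT2+ libraries. No list passed under any list alternative. Over 3781 pairs of a named gene and an alternative, 3461 kept direction and side of the threshold, 272 changed direction with no call on either side, 28 gained and 20 lost a call, and none reversed a call.

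With a replicate block, FOXO1 was no longer called in 3D (0 genes toward TNNT2-) and KDM5B was (1 gene toward TNNT2+), and it changed no other call of genes, guides or lists in the sorts and the difference between systems.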

Other observations

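The tests of the thin libraries (losses in 3D culture 3 included), of FOXO1's 3D libraries, strongest guide and shared shift, and of the noise of day 0 replicate 2 were chosen after the results were seen. Those of guide abundance, of abundance at day 0 and of other splits were written before their own values were seen, although the FOXO1 and essential factor patterns behind the former 2 were already known.

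Guide representation was low in day 0 replicate 2, 3D TNNT2- replicate 3 and 3D TNNT2+ replicate 3. Too few reads is argued against, as the smallest of their totals was 1.10 times the smallest of the other 11. Loss from the differentiated stem cells is argued against for day 0 replicate 2, since a mean of 97.2% of its 3692 guides under 10 reads had at least 10 reads in a 2D library. A loss only in the cells sampled as day 0 replicate 2 is not covered by this and stays open. Among guides under 10 reads, reads followed the mean level in the other libraries (median Spearman rho = 0.555), which is consistent with few DNA templates sampled and stray reads from other libraries of the pool. Loss of guides from the whole of 3D culture 3 before the sort is argued against as the whole cause. Of 3138 guides under 10 reads in its TNNT2- library, 40.9% were present in its TNNT2+ library, with a median of 2558 reads. Over all guides, 43.6% were under 10 reads in that TNNT2+ library. Low reads in both were found for 1856 guides, against 1720 expected at like mean levels. The odds ratio was 1.36 (95% interval 1.24 to 1.49), above 1, so a smaller shared loss may remain. It lay just under the bound of 1.5, which adds no support as it was set after results were seen. A bottleneck after the sort, or few surviving clones that each fell into 1 fraction, stays open, as does the 3D system itself, which was not tested.

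FOXO1 guides were higher in TNNT2- cells of both systems, without passing in 2D with all libraries. Replicate 3 in 2D did not share this, as guides 2, 4, 5 and 6 were lower in its TNNT2- library. Guides 3 and 7 were higher there, and guide 1 was level (284.6 against 284.4 CPM). In 3D replicate 3, guides 3, 4, 6 and 7 were lower in the TNNT2- library and guides 1, 2 and 5 higher. In replicates 1 and 2 of both systems every guide was higher in TNNT2-, except guide 7 in 2D replicate 1 (0 against 9.78 CPM). Guide 7 was near 0 in 3D replicate 2 (0.0844 against 0 CPM). Without the 3 thin 3D libraries the median was 0.89 ± 1.21, against 0.86 ± 2.09 with them, and the call ended after adjustment over genes. The unadjusted p of limma and rank aggregation in the fit without them was 0.000730. It compares FOXO1 with random guide sets and permutes no libraries, so it is not evidence across replicates. That fit has 1 TNNT2- library, with no spread of its own, so it leaves the thin libraries open as a cause of the 3D call. Without each gene's strongest guide the larger p of both systems was 0.000720 by limma and rank aggregation, which argues against 1 expanded guide. In a fit of both systems together, a share of 1e-05 of abundance-matched guide sets ranked as high, the smallest that 100000 sets can give. This argues against abundance in that fit. These 2 values also permute no libraries, so neither is evidence across replicates. The fit of both systems together gave 0.62 ± 1.20 and an adjusted p of 0.0162 by limma and rank aggregation, and with culture as a block 0.486. A shared shift in the ratio of FOXO1 guides toward TNNT2- cells may thus exist as a hypothesis that these data do not settle. The ratio alone does not show that cells left the TNNT2+ fraction.

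Guides against 21 commonly essential transcription factors were not shown to be lower than control guides at day 25 against day 0. Their difference from control guides was -0.053 log2 units in 2D (95% bootstrap interval over genes -0.516 to 0.404) and -0.0086 in 3D (-0.533 to 0.644). Without day 0 replicate 2 it was -0.101 in 2D (-0.294 to 0.146) and 0.0068 in 3D (-0.411 to 0.293). Leaving that library out thus uncovered no loss, but the intervals are too wide to exclude one. Whether its noise hid a loss was not settled. At day 0 (replicate 1) they already lay -0.399 from control guides (-0.624 to -0.160), an interval on both sides of the bound of -0.5 set beforehand, so loss before day 0 cannot be told apart from other sources of unequal abundance. Editing was not measured, and weak or late editing may also contribute.

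Other splits of the samples are too few for a share under 0.05. In the 2D sort all 10 splits called at least the real 0 genes, and the highest other split called 1. In the 3D sort only the real split, 1 of 10, called 1 gene, and the highest other called 0. Of these splits, 4 part all 3 same-numbered pairs, the real one included, and the other 6 part only 1. In 3D neither kind called a gene besides the real split, and the call in 2D came from a split that parts 1 pair. For the difference between systems all 10 splits called 0 genes.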
